A study of Mus musculus with 6 samples.

How the data were processed

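RNA was measured in cultures of the mouse embryonic stem cell line W4 that had been differentiated towards neurons for 16 days. Valproate (VPA), an antiepileptic drug that inhibits histone deacetylases, was present at 300 uM throughout in 1 group. The other group received phosphate-buffered saline (PBS), the solvent. Each group had 3 arrays, and the design text describes them as biological replicates. Per the labels' protocols, total RNA was extracted with Trizol and turned into biotin-labelled sense-strand DNA by the Affymetrix whole transcript assay.

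The values used were the normalized log2 signals per probe set that the authors deposited, 1 column per array. Base 2 was inferred from their range, 2.50 to 13.89, with array medians between 6.99 and 7.03. Background correction, summarization and the method of normalization are not given in the sources used here. Partek 6.5 and genome build mm9 are named in the submitters' processing notes, with no role stated. The array medians are nearly equal, and normalization of arrays to each other removes overall differences in RNA content between groups, so each change below is relative to the other genes. The values came with no detection calls, scan dates or batches, and these were not used here. For arrays, the number of arrays limits the precision.

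The table held 35556 probe sets. GEO's platform annotation gave exactly 1 gene symbol for 21789 of them, several for 1621 and none for 12146 (34.2%). Symbols were updated through the Entrez gene ID, which matched a RefSeq gene table of a later build for 21698 of the single-symbol probe sets and did not for 91. No coordinates from that table were used. Each gene was represented by its probe set with the highest mean over all 6 arrays, which gave 19938 genes, 999 of them with more than 1 probe set. No gene was named from a probe set with several symbols.

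VPA was compared with PBS on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), at a Benjamini-Hochberg adjusted p under 0.05. The count of probe sets was adjusted over the 23410 probe sets with at least 1 symbol, and the counts of genes over the 19938 genes. Changes are VPA minus PBS, with the moderated standard error (SE) from the same fit. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so none was reported for single genes. Lists of marker and pathway genes, 40 in all, were fixed before the data were examined, and 713 of their 773 entries were measured. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, which asks whether its members moved against the other genes, and again with the correlation estimated from the arrays. The p-values of the lists were adjusted over the 40 lists.

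The genes named were chosen by a rule fixed before the data were examined. They were the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, leaving out genes with only a clone, locus or predicted name. For each list, up to 4 members past the threshold with the largest change were selected, or the 2 with the smallest p where none passed; for some lists that were not shifted, not all of these are described. Tubb3, Map2, Gfap, Nes, Pou5f1, Nanog, Hdac1, Hdac2, H1f0 and Cdkn1a were to be named in any case. H1f0 and Cdkn1a were not analysed here, since no probe set was paired with either alone. Genes named outside this rule are said to be chosen after their values were seen.

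In tests on simulated arrays, which used the means and residual spreads of the 19938 genes with 200 genes changed, the VPA against PBS fit recovered 12% of genes changed by 0.25 on the log2 scale, 68% at 0.5, 96% at 1 and 100% at 2. Of its calls 2.82% were false. The data held far more calls, 5825 genes, and the threshold on the unadjusted p is looser where more genes change. These shares therefore do not give the recovery or the false calls of the real comparison. The list test recovered 5 of 5 lists shifted by 0.5 and called 0 of 35 unshifted lists, with genes simulated as independent.

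The alternatives were quantile normalization, centring of each array on its median, filters on dim probe sets at the 30th and 50th percentiles, other variance models, array weights, the replicate number as a block, other thresholds, all probe sets, the mean of a gene's probe sets, other list tests, and leaving out each array in turn. A filter at the 95th percentile of the olfactory receptor genes, which served as a gauge of background signal, and the list counts without VPA replicate 1 were added after seeing the data.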

Results

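Expression was measured on 6 arrays, 3 of cultures given 300 uM VPA and 3 of cultures given PBS, after 16 days of neural differentiation of W4 mouse embryonic stem cells. The comparison asked which transcripts differed when a developmental neurotoxicant was present, at a dose the labels call sub-toxic, while neurons formed. Array medians lay between 6.99 and 7.03 on the log2 scale. Over all genes, the median absolute difference between PBS arrays was 0.06 to 0.07, and that between VPA replicates 2 and 3 was 0.07. VPA replicate 1 lay further from these, at 0.12 from VPA replicate 2 and 0.13 from VPA replicate 3.

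With VPA, 21 of 21 genes of fibroblasts and extracellular matrix rose, as did 23 of 29 cell cycle genes, 17 of 22 genes of BMP and TGF-beta signalling and 24 of 27 genes of a hindbrain and spinal list that is mostly Hox genes. Of the presynaptic and postsynaptic genes 12 of 20 and 13 of 20 fell. In the voltage-gated channel list 9 of 20 fell and 3 rose, and of forebrain patterning genes 10 of 19 fell and 3 rose. These lists were shifted against the other genes by limma's camera at its preset correlation, but 0 of 40 lists passed with an estimated correlation, where the lowest adjusted p was 0.205. Of 19938 genes, 5825 (29.2%) differed at an adjusted p under 0.05, with 2702 higher and 3123 lower. Most changes were small. Among the genes that passed, 695 were at least 1.5-fold higher and 432 at least 1.5-fold lower, and 231 and 100 changed at least 2-fold up and down. A rise of at least 4-fold was measured for 29 genes and such a fall for 5. At the level of probe sets, 6640 of 23410 passed, 3190 higher and 3450 lower. The values of the groups did not overlap for 8775 genes (44.0%), where chance gives 10%. The median change over all genes was 0.0013. After quantile normalization the balance of calls turned, with 3147 genes higher and 2671 lower. On the deposited values, leaving out any 1 array other than VPA replicate 1 lowered the counts, and leaving out VPA replicate 1 raised them. Without PBS replicate 2, which moved both gene counts by over 1.5 times, 1778 genes were higher and 2058 lower, and 4273 probe sets passed. Without PBS replicate 1 these counts were 1820, 2139 and 4358, and without PBS replicate 3 they were 1972, 2087 and 4577.

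Among the 12 genes with the largest rises, Actc1, which encodes cardiac alpha-actin, went from 7.27 ± 0.18 with PBS to 10.20 ± 0.41 with VPA (log2, SD, n = 3), a change of 2.93 (SE 0.18, adjusted p = 9.26e-06). Postn, which encodes the matrix protein periostin, rose from 8.65 ± 0.30 to 11.31 ± 0.06, by 2.66 (SE 0.13, adjusted p = 2.79e-06). Crabp2, which encodes a carrier of retinoic acid into the nucleus, rose by 2.61 (SE 0.08, adjusted p = 5.79e-07), and Igf1, an insulin-like growth factor, by 2.53 (SE 0.07, adjusted p = 3.93e-07). Hoxb3 rose by 2.59 (SE 0.17). The small leucine-rich matrix proteoglycan genes Aspn and Ogn rose by 2.86 (SE 0.14) and 2.32 (SE 0.07), and Efemp1, which encodes an extracellular matrix glycoprotein, by 2.34 (SE 0.09). Cnn2, a calponin gene of the actin cytoskeleton, rose by 2.64 (SE 0.10), Rtl3 by 2.80 (SE 0.10), Moxd1 by 2.40 (SE 0.08) and the amino acid transporter gene Slc38a4 by 2.35 (SE 0.06). With PBS, the means of Aspn, Rtl3, Slc38a4 and Ogn lay below 6.155, the 95th percentile of the olfactory receptor genes. Those 1027 genes are mostly silent outside the nose, and a level below that value was not told apart from background here. Where 1 group's mean lay below it, here and in later paragraphs, the printed change is the measured difference, and neither its true size nor its rank is defined.

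The largest measured fall was that of a signalling gene. Rspo2, a secreted enhancer of Wnt signalling, fell from 8.88 ± 0.37 with PBS to 6.41 ± 0.27 with VPA (log2, SD, n = 3), a change of -2.46 (SE 0.18, adjusted p = 2.55e-05). Cbln2, which encodes a synapse-organizing protein, went from 9.34 ± 0.11 to 7.17 ± 0.09, a change of -2.17 (SE 0.08, adjusted p = 7.95e-07). Wnt8b, a Wnt ligand of the dorsal forebrain, changed by -2.13 (SE 0.10), Lgi1, an epilepsy gene whose secreted product acts at synapses, by -2.03 (SE 0.09), and Sphkap by -2.06 (SE 0.06). The transcription factor genes Eomes, Zic4 and Dmbx1 changed by -1.95 (SE 0.09), -1.88 (SE 0.09) and -1.84 (SE 0.08); with the mean of a gene's probe sets, the change of Zic4 was -0.88. Ttr, which encodes transthyretin, changed by -1.90 (SE 0.17), the long non-coding RNA gene Lncenc1 by -1.86 (SE 0.09), Rasgrp1 by -1.76 (SE 0.11) and the microRNA gene Mir135a-2 by -1.75 (SE 0.08). With VPA, the means of Wnt8b, Lgi1 and Mir135a-2 lay below the same background gauge of 6.155.

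**Figure D1:**
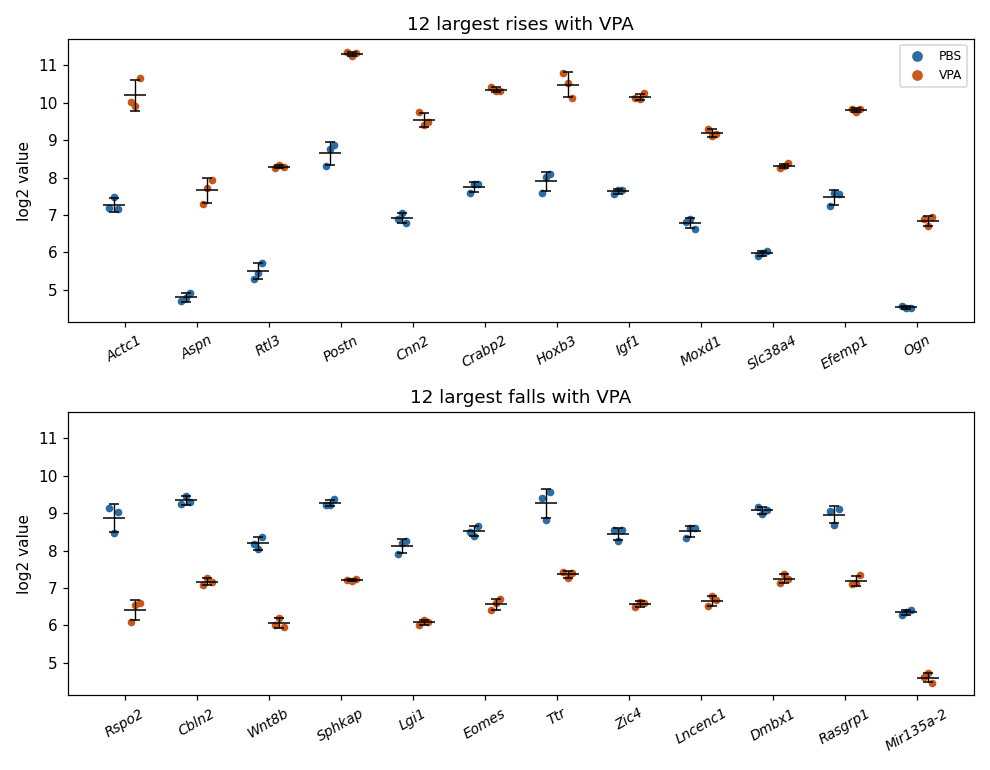
Log2 values of the 12 genes with the largest rises (upper panel) and the 12 with the largest falls (lower panel), for 3 PBS arrays (blue) and 3 VPA arrays (orange), with the mean and SD of each group in black. In each gene the 3 VPA values lie on one side of the 3 PBS values, as the rule for naming required.

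Of the 40 gene lists, 19 were shifted against the other genes at the preset correlation of 0.01, 12 upward and 7 downward. With an estimated correlation 0 of 40 passed limma's camera test, 7 had an unadjusted p under 0.05, and the lowest adjusted p was 0.205. Among the 19 shifted lists the estimate was above the preset except for the postsynaptic (-0.0352) and cholinergic and motor neuron (-0.0582) lists. Their unadjusted camera p still went from 3.46e-07 to 0.00512 and from 0.0104 to 0.0534. For these lists a higher correlation therefore did not account for the loss. By fry, which tests whether the members of a list move one way on balance, 26 passed. Of these, 9 had not passed camera at the preset correlation, and 2 lists that had, pan-neuronal genes and Notch genes, did not pass fry. Each shifted list below is given with both camera values, and an adjusted p without another name is camera's at the preset correlation.

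Every measured gene of the fibroblast and extracellular matrix list rose, 21 of 21, with a median change of 1.10 (adjusted p = 4.18e-19 at the preset correlation, adjusted p = 0.223 with an estimated correlation). The count was 21 adjusted over the list alone. Besides Postn, the members with the largest changes were Lum and Dcn, which encode collagen-binding proteoglycans and rose by 2.29 (SE 0.12) and 2.28 (SE 0.10), and Prrx1, a transcription factor gene of limb and craniofacial mesenchyme, which rose by 1.90 (SE 0.07). Markers of other cell types outside the neural lineage were measured beside these. Of 13 endothelial genes 11 rose, and 11 did adjusted over the list alone (median 0.29, adjusted p = 4.76e-06, adjusted p = 0.223 with an estimated correlation); the median was 0.53 among those at or above the background gauge. The endothelial members were higher in VPA replicate 1 by a median of 0.11. The vessel cadherin gene Cdh5 rose by 1.98 (SE 0.16), Emcn by 1.30 (SE 0.12), Cldn5 by 0.62 (SE 0.08) and Pecam1 by 0.58 (SE 0.08). With PBS, the means of Cdh5 and Emcn, 6.09 and 5.87, lay below 6.155 and were not told apart from background.

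In the cardiac and smooth muscle list 8 of 20 rose and 1 fell, 9 and 1 adjusted over the list alone, 10 and 0 without VPA replicate 1 (median 0.11, mean 0.51, adjusted p = 0.00152, adjusted p = 0.317 with an estimated correlation). The median was 0.30, 1.37 and 0.39 under filters on dim genes at the 30th and 50th percentiles of mean level and at the gauge, below which 7 of the 20 members lay. Myl4 rose by 2.22 (SE 0.18), Acta2, the smooth muscle actin gene that myofibroblasts also express, by 1.84 (SE 0.14) and Tnnt2 by 0.89 (SE 0.10). In the skeletal muscle list 8 of 16 rose and 0 fell, as adjusted over the list alone (median 0.22, adjusted p = 0.00152, adjusted p = 0.423 with an estimated correlation). Over this list VPA replicate 1 differed from the mean of the other VPA arrays by a median of -0.11. Its members Myl1 and Myh3 rose by 2.31 (SE 0.21) and 1.77 (SE 0.15), followed by Chrna1 at 0.58 (SE 0.08) and Acta1 at 0.49 (SE 0.08). With PBS, Myl1, Myh3 and Chrna1 had means of 5.30, 5.21 and 5.71, not told apart from background, and of the 16 members 7 lay below the gauge. The skeletal muscle shift did not pass when genes below the gauge were left out, a filter chosen after seeing the data (median 0.03, adjusted p = 0.0529); the median was 0.34 with the filter at the 30th percentile and 0.14 without VPA replicate 3. In the neural crest list 9 of 14 rose and 2 fell, as adjusted over the list alone (median 0.61, adjusted p = 0.00152, adjusted p = 0.258 with an estimated correlation). Erbb3 rose by 1.62 (SE 0.07) and Snai2 by 1.29 (SE 0.09), while Tfap2b and Pax7, which are also expressed in the dorsal midbrain, changed by -1.39 (SE 0.07) and -1.30 (SE 0.08). The PBS mean of Snai2, 5.75, lay below the gauge, and the neural crest shift did not pass with a filter at the 50th percentile of mean level (adjusted p = 0.0814).

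The hindbrain and spinal list held 25 Hox genes of paralogue groups 1 to 9, which set position along the body axis, with Gbx2 and Egr2. Of these 27 genes 24 rose, 25 adjusted over the list alone, and 0 fell (median 1.13, adjusted p = 4.1e-16, adjusted p = 0.252 with an estimated correlation). Of the 25 Hox genes 23 rose, and Gbx2, named here after its values were seen, rose by 0.40 (SE 0.06). Besides Hoxb3, Hoxb4 rose by 2.13 (SE 0.13) and Hoxb2 by 2.01 (SE 0.18). Hoxc6 rose too, with a measured difference of 2.26 (SE 0.18) from a PBS mean of 6.05, below the gauge. Within the VPA group the members were higher in VPA replicate 1 than in the mean of the other VPA arrays, by a median of 0.36. Without VPA replicate 1, 25 of 27 rose. Of forebrain patterning genes 3 of 19 rose and 10 fell, as adjusted over the list alone (median -0.28, adjusted p = 0.0169, adjusted p = 0.252 with an estimated correlation). The shift did not pass without VPA replicate 1 (adjusted p = 0.0712), although 10 members fell there too (VPA replicate 1 differed from the mean of the other VPA arrays by a median of -0.10 over the list), nor by camera on ranks (adjusted p = 0.0781), and the median was -0.68 with the filter at the 50th percentile. Otx1, Fezf2, Otx2 and Barhl2, transcription factor genes of the anterior brain, changed by -1.60 (SE 0.12), -1.25 (SE 0.09), -1.24 (SE 0.11) and -1.14 (SE 0.06). The midbrain and dopaminergic list did not pass camera (adjusted p = 0.101) but passed fry (adjusted p = 0.0329), with 7 of 15 members higher and 3 lower, as adjusted over the list alone. In it En2, which marks the midbrain-hindbrain boundary, changed by -1.18 (SE 0.06), while Ddc, Th and Pax8 rose by 0.91 (SE 0.10), 0.80 (SE 0.12) and 0.80 (SE 0.13); the PBS mean of Ddc, 5.35, lay below the gauge, and the call of Pax8 was lost without moderation of the variances (adjusted p = 0.0525).

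**Figure D2:**
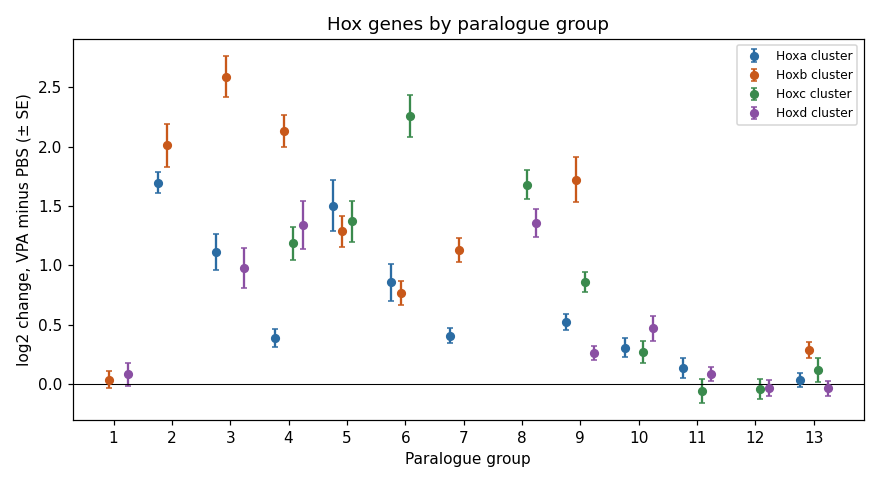
Log2 change (VPA minus PBS) of each measured Hox gene, with its SE, against its paralogue group, coloured by cluster; 3 arrays per group. All 23 genes of groups 2 to 9 rose, from 0.26 to 2.59, and the median of the 9 genes in groups 11 to 13 was 0.04.

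In the presynaptic list 12 of 20 fell and 0 rose, and 15 fell adjusted over the list alone (median -0.29, adjusted p = 2.51e-07, adjusted p = 0.252 with an estimated correlation). The presynaptic members were higher in VPA replicate 1 than in the mean of the other VPA arrays by a median of 0.12, and 18 fell without that array. Rims1, which encodes an active zone scaffold, changed by -0.91 (SE 0.06), Nrxn3 by -0.73 (SE 0.07), Pclo by -0.66 (SE 0.08) and Sncb by -0.62 (SE 0.08). Of 20 postsynaptic genes 13 fell and 0 rose, against 13 and 1 adjusted over the list alone and 15 and 1 without VPA replicate 1 (median -0.34, adjusted p = 2.31e-06, adjusted p = 0.205 with an estimated correlation). The glutamate receptor genes Gria1 and Grm5 changed by -1.51 (SE 0.06) and -1.47 (SE 0.07), and the scaffold gene Dlg2 by -0.89 (SE 0.07). The GABA receptor gene Gabra2 went from 8.64 ± 0.06 with PBS to 7.64 ± 0.15 with VPA (log2, SD, n = 3). In the voltage-gated channel list, which also held the inward rectifier gene Kcnj3, 9 of 20 fell and 3 rose, 10 and 3 adjusted over the list alone (median -0.20, adjusted p = 0.00152, adjusted p = 0.317 with an estimated correlation). The potassium channel gene Kcnd2 changed by -1.71 (SE 0.09), and Cacna1e, Cacnb4 and Scn3a by -0.80 (SE 0.07), -0.70 (SE 0.07) and -0.63 (SE 0.07).

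In the pan-neuronal list 10 of 20 fell and 2 rose, as adjusted over the list alone (median -0.19, adjusted p = 0.0465, adjusted p = 0.555 with an estimated correlation). The shift did not pass without PBS replicate 2 (adjusted p = 0.107), VPA replicate 2 (adjusted p = 0.0749) or VPA replicate 3 (adjusted p = 0.102), nor after quantile normalization (adjusted p = 0.0935). It was also lost with the mean of probe sets (adjusted p = 0.0519), by fry (adjusted p = 0.124) and under filters on dim genes at the 30th and 50th percentiles and at the gauge (adjusted p = 0.129, 0.199 and 0.141). The pan-neuronal members were higher in VPA replicate 1 by a median of 0.10, and 12 fell without it. The tau gene Mapt changed by -0.53 (SE 0.08) and L1cam by -0.48 (SE 0.11), the latter call lost without moderation of the variances (adjusted p = 0.0941), whereas the neurofilament genes Nefm and Nefl rose by 1.24 (SE 0.06) and 0.53 (SE 0.06). Tubb3, a neuronal tubulin gene, changed by -0.27 (SE 0.06, adjusted p = 0.00672). Map2 changed by -0.20 (SE 0.05, adjusted p = 0.0198), a call lost without PBS replicate 1 (0.0501), PBS replicate 2 (0.0935), PBS replicate 3 (0.0716) or VPA replicate 2 (0.0613).

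Of 14 GABAergic genes 5 rose and 4 fell, as adjusted over the list alone, and the list passed neither camera (adjusted p = 0.71) nor fry (adjusted p = 0.836). Gad2 and Gad1, which encode the enzymes that make GABA, changed by -1.48 (SE 0.08) and -1.47 (SE 0.07), while Npy and the homeobox gene Dlx1 rose by 1.67 (SE 0.08) and 1.41 (SE 0.08). Of 11 glutamatergic genes 3 rose and 5 fell, as adjusted over the list alone; the list did not pass camera (adjusted p = 0.293) but passed fry (adjusted p = 0.00314). The vesicular glutamate transporter gene Slc17a6 changed by -1.02 (SE 0.11), Tbr1 by -0.87 (SE 0.09), Nrn1 by -0.60 (SE 0.09) and Slc1a1 by -0.55 (SE 0.06); the VPA mean of Tbr1, 5.78, lay below the gauge. The cholinergic and motor neuron list was shifted upward with 6 of 13 higher and 2 lower, 7 and 2 adjusted over the list alone (median 0.26, adjusted p = 0.0244, adjusted p = 0.252 with an estimated correlation). This shift did not pass under the filters on dim genes at the 30th and 50th percentiles and at the gauge (adjusted p = 0.141, 0.315 and 0.141), where the medians were 0.26, 0.35 and 0.26; 4 of its 13 members lay below the gauge, and the members were higher in VPA replicate 1 by a median of 0.11. Its largest change was that of Lhx1, at -1.06 (SE 0.07); Slc18a3, which encodes the vesicular acetylcholine transporter, rose by 0.61 (SE 0.13), a call lost without moderation of the variances (adjusted p = 0.095), and Phox2a by 0.43 (SE 0.07). Tbx20 differed by 0.46 (SE 0.07), but its means of 5.19 with PBS and 5.65 with VPA both lay below the gauge, so its expression was not told apart from background. In the axon guidance list 10 of 30 rose and 9 fell, as adjusted over the list alone (adjusted p = 0.635), with Unc5d at -1.61 (SE 0.08), Ntn1 at 1.46 (SE 0.22), Slit3 at 1.13 (SE 0.13) and Sema3d at 1.13 (SE 0.09), whose PBS mean of 5.68 lay below the gauge. The call of Ntn1 was lost without moderation of the variances (adjusted p = 0.0521).

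Of 18 progenitor and radial glia genes 6 rose and 4 fell, 8 and 4 adjusted over the list alone, and the list passed neither camera (adjusted p = 0.401) nor fry (adjusted p = 0.225). Id4 changed by -0.85 (SE 0.08), and Hopx, Pax6 and Dach1 rose by 0.63 (SE 0.07), 0.54 (SE 0.07) and 0.54 (SE 0.06). Nes, which encodes the intermediate filament nestin, rose by 0.38 (SE 0.09, adjusted p = 0.0122), a call lost without PBS replicate 2 (adjusted p = 0.0547) and without moderation of the variances (adjusted p = 0.0926). Of 17 neurogenic commitment genes 5 rose and 4 fell, against 5 and 5 adjusted over the list alone, again without passing camera (adjusted p = 0.538) or fry (adjusted p = 0.079). Besides Eomes, Neurod1 changed by -0.62 (SE 0.07) and Gadd45g by -0.38 (SE 0.08), and Neurog1 rose by 0.60 (SE 0.16, adjusted p = 0.0212), a call lost without PBS replicate 1 (0.0723), PBS replicate 2 (0.0524) or PBS replicate 3 (0.0695). Without moderation of the variances the calls of Neurog1 and Gadd45g were lost (adjusted p = 0.156 and 0.0733), and without VPA replicate 1 Neurog1 changed by 0.38. Of 18 astrocyte genes 6 rose and 5 fell, 7 and 5 adjusted over the list alone (camera adjusted p = 0.327, fry adjusted p = 0.0444), with Fgfr3 at 0.98 (SE 0.09), Sparcl1 at 0.79 (SE 0.07), Mlc1 at -0.77 (SE 0.11) and Nfia at 0.50 (SE 0.05). Gfap changed by -0.27 (SE 0.08, adjusted p = 0.041), a call that held only without VPA replicate 2 among the 6 fits with an array left out; without PBS replicates 1, 2 and 3 the adjusted p was 0.0821, 0.0646 and 0.153, and without VPA replicates 1 and 3 it was 0.0608 and 0.0787. It was also lost without moderation of the variances (adjusted p = 0.152). Of 17 oligodendrocyte lineage genes 5 rose and 3 fell, 6 and 3 adjusted over the list alone (camera adjusted p = 0.211, fry adjusted p = 0.0402), with Pdgfra, which mesenchymal cells also express, at 1.54 (SE 0.07), Olig1 at -1.07 (SE 0.11), Gpr17 at 1.01 (SE 0.09) and Olig2 at -0.85 (SE 0.14), the last call lost without moderation of the variances (adjusted p = 0.0569).

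Cell cycle genes rose in 23 of 29 cases and 0 fell, 26 and 0 adjusted over the list alone (median 0.46, adjusted p = 3.07e-11, adjusted p = 0.264 with an estimated correlation). Ccne1, the cyclin gene of entry into DNA replication, rose by 0.98 (SE 0.07), the replication helicase gene Mcm6 by 0.74 (SE 0.08), Tyms by 0.65 (SE 0.06) and the mitotic kinase gene Aurkb by 0.57 (SE 0.10), the last call lost without moderation of the variances (adjusted p = 0.051). The pluripotency list did not pass camera (adjusted p = 0.0618 with all arrays), with 4 of 19 higher and 0 lower, 3 and 0 adjusted over the list alone. Its median of 0.11 was 0.03 without PBS replicate 2 (adjusted p = 0.19) and 0.05 without VPA replicate 2 (adjusted p = 0.155). It passed without PBS replicate 3 (median 0.18, adjusted p = 0.018), without VPA replicate 3 (adjusted p = 0.0428), with array weights (adjusted p = 0.0319) and by camera on ranks (adjusted p = 0.0413). Of the 19 members 13 lay below the gauge, and the median was 0.03 without them. Tbx3 rose by 0.65 (SE 0.06). The other 3 counted as higher were Lefty2 and Dppa2, below the gauge in both groups, and Klf4, below it with PBS. The call of Lefty2 was lost without PBS replicates 1 and 3 and VPA replicate 3 (adjusted p = 0.0755, 0.0723 and 0.0529), that of Klf4 without each PBS array in turn (adjusted p = 0.0604, 0.0648 and 0.0628), and that of Dppa2 without each array but VPA replicate 1 (adjusted p = 0.0667 to 0.149). Without moderation of the variances the calls of Lefty2 and Dppa2 were also lost (adjusted p = 0.109 and 0.186). With the mean of its probe sets Dppa2 differed by 0.13 (adjusted p = 0.365). Nanog differed by 0.19 (SE 0.11, adjusted p = 0.217), by 0.33 with array weights (adjusted p = 0.0132) and by 0.08 without VPA replicate 2 (adjusted p = 0.59). Pou5f1 differed by -0.02 (SE 0.09, adjusted p = 0.91), by -0.13 without PBS replicate 2 and by 0.04 without PBS replicate 1. Both genes lay below the background gauge in both groups.

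Several signalling lists were shifted upward. Of 22 BMP and TGF-beta genes 17 rose and 0 fell, as adjusted over the list alone (median 0.41, adjusted p = 1.08e-07, adjusted p = 0.223 with an estimated correlation). Tgfb3 rose by 1.48 (SE 0.09), Bmp5 by 1.37 (SE 0.11), Tgfbi by 1.24 (SE 0.13) and Id1, a direct target of BMP signalling, by 0.91 (SE 0.11). Of 12 Hedgehog genes 7 rose and 0 fell, as adjusted over the list alone (median 0.29, adjusted p = 0.00152, adjusted p = 0.469 with an estimated correlation). The pathway's target genes Ptch1, Hhip and Gli1 rose by 1.04 (SE 0.12), 0.97 (SE 0.07) and 0.70 (SE 0.06), and the ligand gene Shh by 0.53 (SE 0.09). The Hedgehog members were higher in VPA replicate 1 than in the mean of the other VPA arrays by a median of 0.22. Of 17 Notch genes 7 rose and 0 fell, as adjusted over the list alone (median 0.25, adjusted p = 0.00779, adjusted p = 0.555 with an estimated correlation), with Heyl at 0.86 (SE 0.08), Hey1 at 0.57 (SE 0.11), Hes1 at 0.45 (SE 0.08) and Dll4 at 0.41 (SE 0.06); the call of Hey1 was lost without moderation of the variances (adjusted p = 0.0712). These members too were higher in VPA replicate 1, by a median of 0.24. Without VPA replicate 1 the Notch shift did not pass (median 0.12, adjusted p = 0.0903), and 7 rose and 3 fell; nor did it pass fry (adjusted p = 0.0553), and with array weights the median was 0.15. Of 29 Wnt genes 14 rose and 7 fell, 14 and 8 adjusted over the list alone, and the list did not pass camera (median 0.16, mean 0.0096, adjusted p = 0.155) but passed fry (adjusted p = 0.0153) and camera with a filter at the 50th percentile of mean level (adjusted p = 0.0397); without PBS replicate 1 the median was 0.09. Besides Rspo2 and Wnt8b, Rspo3 changed by -1.65 (SE 0.17), and Dkk2 rose by 1.32 (SE 0.09).

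VPA inhibits histone deacetylases, and genes of that class were measured directly. In the list of histone deacetylases and acetyltransferases, which also held the bromodomain gene Brd2, 1 of 21 rose and 5 fell, as adjusted over the list alone (median -0.12, adjusted p = 0.0437, adjusted p = 0.469 with an estimated correlation). The shift did not pass without PBS replicate 3 (adjusted p = 0.0533), VPA replicate 2 (adjusted p = 0.0639) or VPA replicate 3 (adjusted p = 0.107), nor after quantile normalization (adjusted p = 0.115) or under the filters on dim genes at the 30th and 50th percentiles and at the gauge (adjusted p = 0.126, 0.199 and 0.141). With VPA replicate 1 left out, 9 members fell. Kat6b and Kat2b changed by -0.48 (SE 0.07) and -0.46 (SE 0.06), and Hdac11 by -0.31 (SE 0.07). Hdac1 rose by 0.36 (SE 0.06, adjusted p = 0.00232), and Hdac2 differed by -0.18 (SE 0.08, adjusted p = 0.116), or by -0.09 without VPA replicate 1. Of 11 genes known to rise with histone deacetylase inhibitors 8 rose and 2 fell, as adjusted over the list alone (median 0.34, adjusted p = 0.00152, adjusted p = 0.223 with an estimated correlation). Gsn, which encodes gelsolin, rose by 0.72 (SE 0.06), and Ccnd2, Mt2 and Cdkn2b by 0.62 (SE 0.06), 0.61 (SE 0.06) and 0.61 (SE 0.08). Tubb3, also on that list, was among the 2 that fell.

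Of 17 hypoxia and glycolysis genes 9 fell and 1 rose, 12 and 2 adjusted over the list alone (median -0.32, adjusted p = 0.00152, adjusted p = 0.469 with an estimated correlation). The phosphofructokinase gene Pfkp changed by -0.93 (SE 0.08), Pdk1 by -0.70 (SE 0.07) and Bnip3 by -0.56 (SE 0.07), while Egln3 rose by 0.54 (SE 0.12), a call lost without moderation of the variances (adjusted p = 0.108). In VPA replicate 1 these genes were higher than in the mean of the other VPA arrays by a median of 0.19, and 2 rose and 12 fell without it. None of the other metabolic and stress lists passed the camera test. In the list of unfolded protein and amino acid stress (adjusted p = 0.491) 3 of 18 rose and 5 fell, 3 and 7 adjusted over the list alone, with Ddit3 at -0.69 (SE 0.08) and Sdf2l1 at 0.74 (SE 0.08). There 5 rose and 8 fell without VPA replicate 1. In the p53 list (adjusted p = 0.202) 5 of 15 rose and 0 fell, in the oxidative stress list (adjusted p = 0.327) 4 of 15 rose and 2 fell, and in the cholesterol synthesis list (adjusted p = 0.168) 2 of 15 rose and 5 fell, each as adjusted over the list alone. Without VPA replicate 1, 2 of the p53 genes fell, 1 of the oxidative stress genes fell and 1 of the cholesterol genes rose. In the fatty acid oxidation list (adjusted p = 0.293) 5 of 21 rose and 3 fell, 7 and 3 adjusted over the list alone. The cystine transporter gene Slc7a11, of the oxidative stress list, changed by -1.12 (SE 0.14). In the immediate early list (adjusted p = 0.128, fry adjusted p = 0.0312) 5 of 16 rose and 1 fell, 7 and 2 adjusted over the list alone, and 2 fell without VPA replicate 1.

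Among the remaining cell type lists, endoderm genes rose in 3 of 17 cases and fell in 2, as adjusted over the list alone (camera adjusted p = 0.293, fry adjusted p = 0.00401), with Dab2 at 1.85 (SE 0.08), or 0.96 with the mean of its probe sets; without VPA replicate 1, 5 rose. Epithelial genes rose in 3 of 16 cases and fell in 1, as adjusted over the list alone (camera adjusted p = 0.154, fry adjusted p = 0.0114), with Krt8 at 0.56 (SE 0.09). In the choroid plexus list 1 of 11 rose and 3 fell, as adjusted over the list alone (camera adjusted p = 0.202, fry adjusted p = 0.0312, camera with a filter at the 50th percentile adjusted p = 0.0277), and 2 of those that fell, Ttr and Otx2, are also on other lists. In the fit without VPA replicate 1, 2 rose. Of 17 blood and microglia genes, 14 of which lay below the gauge, 0 rose and 0 fell, as adjusted over the list alone (adjusted p = 0.803, by limma's camera). The smallest unadjusted p values belonged to Cd68 at -0.22 (SE 0.08, adjusted p = 0.0631) and Cx3cr1 at 0.15 (SE 0.06, adjusted p = 0.108). Without VPA replicate 1 both passed (adjusted p = 0.00244 for Cd68 and 0.029 for Cx3cr1), and 2 members rose and 1 fell. Both also passed with array weights (adjusted p = 0.00236 and 0.0109), and Cd68 under the filters on dim genes at the 30th and 50th percentiles and at the gauge (adjusted p = 0.0489, 0.0428 and 0.0466). Of 12 housekeeping genes 1 rose and 2 fell, as adjusted over the list alone (median -0.06, adjusted p = 0.327). These were B2m at 0.76 (SE 0.07), Pgk1 at -0.53 (SE 0.06) and Tfrc at -0.45 (SE 0.06).

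**Figure D3:**
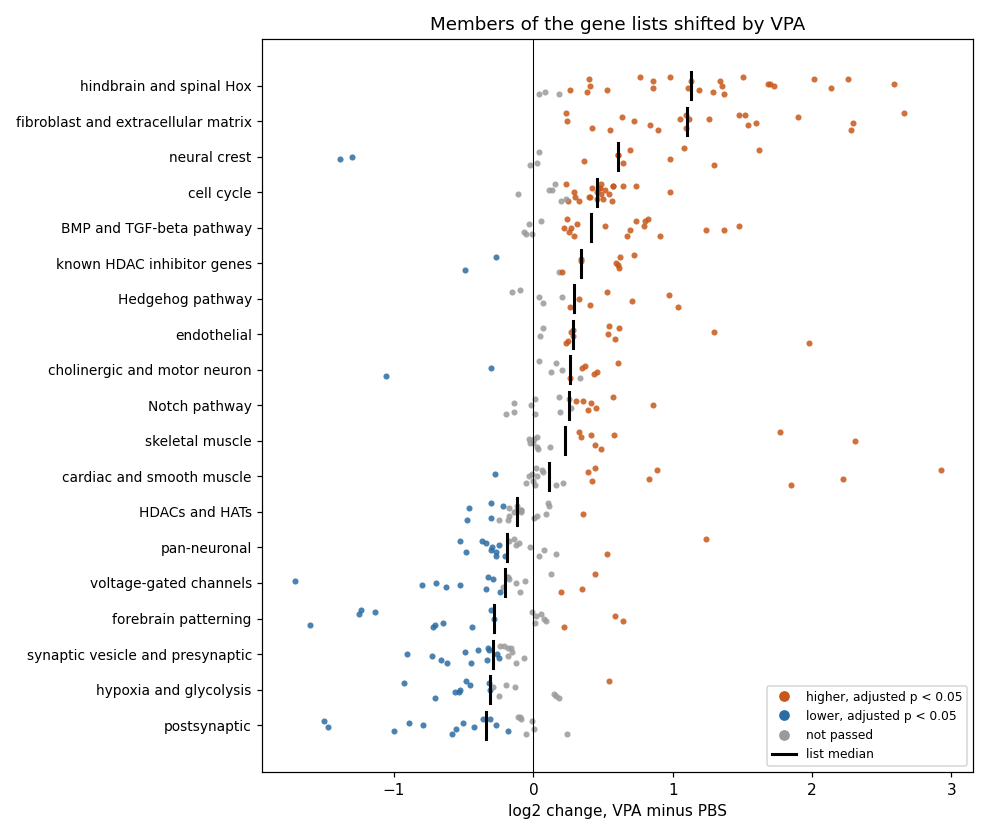
Log2 change (VPA minus PBS) of each measured member of the 19 lists shifted at the preset correlation, in orange where higher and blue where lower at an adjusted p under 0.05 and in grey otherwise, with the list median as a black line; 3 arrays per group. All 21 members of the fibroblast and extracellular matrix list lie above 0, and no list passed with an estimated correlation.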

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

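The tests below of the olfactory receptor genes, the matrix genes and VPA replicate 1 were chosen after the result, or values close to it, had been seen; the counts over other splits of the arrays were planned. Groups of 3 arrays are too small for an outlier test, and none was applied.

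Probe sets without a gene name took no part in the report's comparisons and were tested on their own with limma, adjusted over these 12146 probe sets. At an adjusted p under 0.05, 195 were higher with VPA than with PBS and 581 were lower, and 28 and 66 of these changed at least 2-fold.

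Olfactory receptor genes, taken as a gauge of background, were higher with VPA: 231 of 1027 passed upward and 2 downward, with a median change of 0.18, and 9 changed at least 1.5-fold. Other genes matched to them on mean level, not limited to protein-coding genes, had a median change of only 0.02 (0.0245), and the highest median among 10000 matched random lists was 0.0356, which argues against a rise shared by all dim probe sets. The rise was not limited to olfactory receptor genes either. Medians were 0.19 for trace amine-associated receptor genes, 0.13 for keratin-associated protein genes, and 0.09 for both defensin and vomeronasal receptor genes, none of them tested as a family. After quantile normalization 290 were called higher, among them 226 of the 231. Differences in distribution left between the deposited arrays therefore do not account for the whole. The authors' own scaling could not be undone here and was not tested. A release of silent genes by VPA in every culture stays open: the lowest VPA array median exceeded the highest PBS array median by 0.0164, less than the PBS range of 0.0803. Probe sequence composition was not tested.

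All 21 measured genes of the fibroblast and extracellular matrix list rose. A lower share of neurons alone would raise progenitor markers too, if VPA did not act on those genes themselves, which was not tested. Their upper quartile was 0.423, below the lower quartile of the matrix genes at 0.718. A lower share of neurons and progenitors together is not covered by this comparison. After quantile normalization the list median was 1.14. The deposited arrays were already close to each other, with medians of 6.99 to 7.03, so this step could hardly have moved it. It decides nothing about the authors' own scaling. More mesenchymal cells in the VPA cultures and induction within cells both stay open: the rise of 21 of 21 members was known beforehand and decides nothing between them, and RNA of whole cultures cannot part cell number from level per cell.

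VPA replicate 1 lay apart from the other VPA arrays. In it 53 small nucleolar RNA genes were higher by a median of 0.45 than in the mean of VPA replicates 2 and 3, against -0.02 over protein-coding genes. Another share of small RNA could not account for the whole, since over protein-coding genes the smaller of its median differences from those arrays was 0.124, against at most 0.0719 for any other pair within a group. A weaker response to VPA would make most changes smaller in it, which argues against it for the 331 genes changed at least 2-fold, of which 24.2% changed less in VPA replicate 1 than in the mean of the other VPA arrays (33.1% if the genes were chosen without that array). For all called genes it stays open, since 47.1% changed less there and 62.0% if chosen without that array. Lists went both ways. The presynaptic, pan-neuronal and hypoxia lists, which were shifted downward, were higher in it by medians of 0.12, 0.10 and 0.19. The skeletal and cardiac muscle lists, shifted upward, differed there by -0.11 and -0.06. The olfactory receptor genes, with a median change of 0.18, differed there by a median of -0.20. Against a weaker response, the upward Hox, Notch, Hedgehog and endothelial lists were higher in it by medians of 0.36, 0.24, 0.22 and 0.11. The downward forebrain list differed there by -0.10, and the postsynaptic list by only -0.0072.

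The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 6640 probe sets, 2702 genes higher and 3123 lower, and 19 lists. Each of the other splits put VPA and PBS arrays together, which widens the spread within a side, so few gene calls could be made there. These splits called 0 probe sets and 0 genes in either direction, yet 7 to 14 lists each. Camera at the preset correlation thus passed lists under groupings where no gene passed. Those splits held unequal numbers of VPA arrays on their 2 sides, 1 or 2 on the first, so part of the VPA difference remained in them. Their list calls therefore give no rate of false calls. They cannot show how many of the 19 lists would pass without an effect of VPA. In each of the 4 counts 1 of 10 splits, the real one, reached the real value.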

How the results depend on the processing

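The filter at the olfactory receptor percentile was chosen after seeing the data. No result changed direction past the threshold. Of the 174 genes past the threshold that the naming rule selected, some of which are not described, 143 kept their call under every alternative in which they were tested. The counts moved by over 1.5 times as follows, and beyond what the construction of a setting shows the cause was not tested. Array weights called 10660 probe sets and 4431 genes higher. Without moderation of the variances 4143 probe sets passed, with 1631 genes higher. At an adjusted p under 0.01, 3672 probe sets passed, 1579 genes were higher and 1791 lower. With at least 1.5-fold these were 1423, 695 and 432, and with an unadjusted p under 0.05 and at least 1.5-fold 1437, 697 and 432. Leaving out an array gave 4273 to 9599 probe sets, 1778 to 3949 genes higher, 2058 to 4224 lower and 17 to 19 lists; the highest counts of probe sets and genes came without VPA replicate 1, where 5720 of the 5825 genes passed with the same sign. Lists numbered 0 with an estimated correlation and 15 to 26 under the other alternatives. Quantile normalization gave 3147 genes higher and 2671 lower, so that 54.1% of calls were higher in place of 46.4%. Arrays with the same replicate number did not deviate together (correlations of -0.02, -0.0085 and 0.02 across genes, which are not independent replicates), and no number paired the arrays. With the replicate number as a replicate block, 6253 probe sets passed, 2592 genes were higher, 2818 lower and 19 lists shifted. Signal near background limits dim genes: 13959 of 19938 genes had a mean at or above the olfactory receptor 95th percentile, and among these 2286 were higher and 3185 lower.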

Other observations

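The gene groups in this part were chosen after the data were seen. Genes of retinoic acid handling and response were higher with VPA in 13 of 19 measured cases, and 0 fell (median 0.70). Besides Crabp2, the retinoic acid carrier gene Crabp1 rose by 1.74 (SE 0.07), the retinol receptor gene Stra6 by 1.32 (SE 0.10), the degrading enzyme gene Cyp26b1 by 0.99 (SE 0.10), the synthesizing enzyme gene Aldh1a2 by 0.95 (SE 0.10), from a PBS mean of 5.21 below the background gauge, and the receptor genes Rara and Rarb by 0.90 (SE 0.13) and 0.70 (SE 0.11). Cyp26a1 differed by -0.04 (SE 0.08, adjusted p = 0.746), with both means below the gauge. Of 37 measured Hox genes 26 rose, 23 of 23 in groups 2 to 9 (median 1.29), 0 of 2 in group 1, 2 of 3 in group 10 and 1 of 9 in groups 11 to 13 (median 0.04). The difference between these groups was not tested. All 4 measured Zic genes, transcription factors of the dorsal neural tube and cerebellum, fell (median -1.12), with Zic5 at -1.42 (SE 0.11), Zic1 at -0.82 (SE 0.08) and Zic2 at -0.82 (SE 0.09).

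Of 11 genes of the insulin-like growth factor system 5 rose and 2 fell (median 0.14). Igf2 rose by 1.87 (SE 0.08), and the binding protein genes Igfbp3 and Igfbp4 by 1.38 (SE 0.10) and 1.37 (SE 0.09). Imprinted genes moved both ways. Of 14 paternally expressed genes 7 rose and 4 fell (median 0.21), with Dlk1 at 1.65 (SE 0.09), Plagl1 at 1.01 (SE 0.07), Magel2 at -0.67 (SE 0.14) and Ndn at -0.35 (SE 0.05). Of 6 maternally expressed genes 2 rose and 2 fell (median -0.02). Of 163 vomeronasal receptor genes 20 rose and 1 fell (median 0.09), and of 44 keratin-associated protein genes 6 rose and 0 fell (median 0.13); no test of either family was made.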
